A study of Homo sapiens with 16 samples.

How the data were processed

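Ribosome footprints were measured in 4 established human cell lines: NCI-H1650 and NCI-H520 (lung cancer), and Hs 936.T and A375 (melanoma). Cells received DMSO or rocaglamide A (RocA) at 0.3 or 3 µM for 30 min, after which RNase I digestion, ribosome pelleting and depletion of ribosomal RNA gave the footprint libraries. Per line there were 2 DMSO libraries and 1 library at each dose, 16 in all. The titles of 2 libraries, DMSO replicate 2 and 3 µM of NCI-H520, name that line while their cell-line label reads NCI-H521; they were grouped by title, and leaving them out was an alternative. No RNA-seq of the same cells was used here, so footprints were not divided by mRNA levels.

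Per the labels, the authors processed reads with CASAVA 1.8, aligned them with Bowtie2 2.1.0 and TopHat2 2.0.9 to hg38, and counted footprints per transcript. The deposited files give, for 182398 transcript entries, an identifier, the number of codons counted and the raw footprint count of the authors, without further normalization. The codons counted are those of the coding sequence less 10, and 88482 noncoding entries hold no counts. Reads are repeated over the transcript entries of a gene. The annotation release behind the identifiers is not given in the sources used here.

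Genes were named by length, not by identifier. Sets of coding lengths over neighbouring entries were matched to the coding transcripts of GENCODE 29, with a minimum score of 14 (natural log) and minimum odds of 100, and the entry with the highest mean count stood for its gene. This named 9562 of 20418 coding genes after 310 were dropped for shared entries. Decoy genes with altered lengths passed in 102 cases against 9880, or 1.03%. The chromosome order of neighbours, not used in the matching, placed 0 named genes off their neighbours' chromosome by this check, against 89.8% after shuffling. Tested on simulated data, 8425 of 19397 genes were matched (43.4%), 0 of them to a wrong gene. Genes with few isoforms or common lengths were less often named, so the named genes are a selected part of the transcriptome. Mitochondrially encoded genes were not named, since the best window held 6 of their 13 lengths; the planned comparison of nuclear with mitochondrially encoded footprints, and scaling to the latter, were therefore not run. Replication-dependent histone genes and EIF4A3 were not analysed here. DDX3Y, being Y-linked, is not reported. Some genes that the naming rule selects, and the outcome with coding length in place of 5' UTR features, are not reported here.

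Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Libraries were scaled by TMM, and genes were kept by filterByExpr over doses with a minimum count of 10 (5964 genes). The dose comparisons used the robust quasi-likelihood test of edgeR with terms for cell line and dose, all tests 2-sided, and a Benjamini-Hochberg adjusted p under 0.05 as a call. Differences of response between lines used a term for each line's response shared by both doses and a common term for 3 against 0.3 µM. The lines under DMSO were compared over the 8 DMSO libraries (7089 genes). DMSO replicate numbers did not pair the lines, with correlations of replicate deviations between -0.03 and 0.09, so no replicate term was fitted. Changes per line are log2 CPM (prior count 2) of the treated library less the mean of its DMSO libraries, and CPM values are means with SD.

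Gene lists were fixed before the data were examined, and 23 with at least 5 tested genes were tested with camera at a preset correlation of 0.01; camera with an estimated correlation and fry were alternatives. Lists of alveolar, neuroendocrine and blood cell genes had fewer than 5 tested genes with RocA and are not reported. Named genes were chosen by a rule also fixed beforehand. Per dose it took the 10 largest rises and falls among called genes with at least 10 CPM on average and the same sign in each line, with members of each list and the helicases beside them. Genes with 0 counts in a group are given as at least a fold, from a floor of 3 counts over the libraries of that group, and those with 1 to 3 counts as a ratio with a 95% counting interval; both cover counting error only. Features of the annotated 5' UTR were correlated with the fold changes over 5957 genes, with 100000 permutations and Benjamini-Hochberg adjustment over 8 tests.

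Depth limits precision. Named-gene totals were 548207 to 3015207 with DMSO and 47366 to 558581 with RocA, and DMSO replicates varied 1.63 to 2.59 times as much as counting error alone (chi-square per degree of freedom), with r of log2 counts across genes from 0.969 to 0.991. On simulated counts with planted changes, a 2-fold change was recovered for 74.6% of genes at 0.3 µM, 73.1% at 3 µM and 40.3% between doses, and for 55.2% and 88.1% between the lung and melanoma lines under DMSO; false calls were 2.07%, 3.57%, 2.15%, 1.82% and 4.85% of calls. A list shifted by 1.5-fold was called by camera, together with 1 of 21 unshifted lists. Simulated genes were drawn independently of each other, so this does not cover lists whose members move together. A planted 5' UTR relation was found (rho 0.18) and 0 of 2 unrelated features had a permutation p under 0.05.

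The alternatives were DESeq2 size factors, the DESeq2 test, limma-voom, no low-count filter, a minimum count of 50, no term for cell line, dose as a score of 0, 1 and 2 or no dose term in the response differences, the compared libraries alone, ribosomal protein genes left out, all entries of a gene summed, each library and each line left out, and both NCI-H521-labelled libraries left out. Chosen after seeing the data were thinning to equal depth within each line, all shared-read loci named or not, leaving out genes mainly of Hs 936.T, the estimated correlation for the DMSO lists, purine 6-mers per 100 nt, and coding length in place of 5' UTR features.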

Results

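Ribosome profiling sequences the mRNA fragments that ribosomes protect from RNase digestion, so the count of such footprints on a gene follows how many ribosomes sat on its mRNA. Footprints were counted in 4 established human cancer cell lines, the lung lines NCI-H1650 and NCI-H520 and the melanoma lines Hs 936.T and A375. Cells were exposed for 30 min to the solvent DMSO or to rocaglamide A (RocA), a plant-derived translation inhibitor that clamps the RNA helicase eIF4A onto purine-rich RNA. Each line gave 2 DMSO libraries, 1 library at 0.3 µM and 1 at 3 µM, 16 libraries in all. The cell lines served as the replicates of each dose (n = 4), and values for a single line and dose have no replicate check. The error of the dose fit also drew on differences between the 2 DMSO libraries of a line. Its SE and p-values therefore do not measure the spread between lines alone. Counts over the 9562 genes that could be named ranged from 548207 to 3015207 per DMSO library and from 47366 to 558581 per RocA library. Relative to the mean of its own DMSO libraries, the treated total was lowest in NCI-H1650 at 3 µM, at 8.5%, and highest in NCI-H520 at 3 µM, at 39.3%. Library totals follow pooling and sequencing as well as translation, and each library was scaled to its own content, so every change below is relative to the other genes of the same library and a change of all genes together was not measured.

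Melanocyte genes served as a check of cell identity. The pigment-cell genes PMEL, TYRP1, DCT and SLC45A2 were abundant in Hs 936.T and almost absent from A375. They were also read in NCI-H520, a lung line, where the median over 9 such genes stood at 3.92% of the Hs 936.T level in DMSO replicate 1 and at 8.32% in DMSO replicate 2. The treated NCI-H520 libraries stood at 0.835% (0.3 µM) and 1.53% (3 µM), and no library of NCI-H1650 or A375 exceeded 0.598%. Within NCI-H520 the median change of 10 melanocyte genes was accordingly -2.27 at 0.3 µM and -1.28 at 3 µM on the log2 scale.

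**Figure D1:**
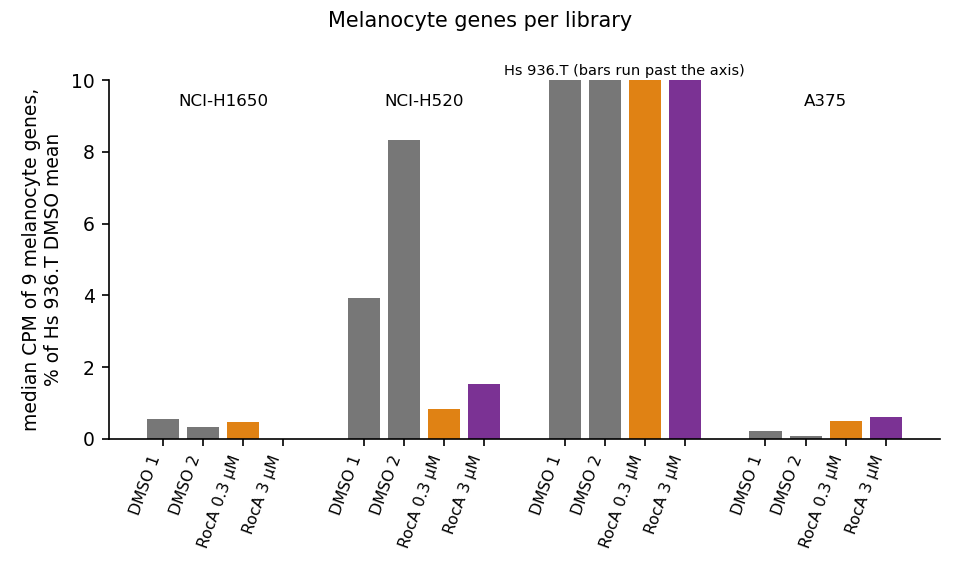
Median level of 9 melanocyte genes in each library (vertical axis, CPM as a percentage of the mean of the Hs 936.T DMSO libraries, linear from 0), grouped by cell line and coloured by treatment; the Hs 936.T bars run past the axis. The NCI-H520 DMSO libraries stand at 3.92% and 8.32%, above every library of NCI-H1650 and A375.

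The series title names DDX3 and eIF4A as targets of the compound, so the footprints on these helicases were compared first. EIF4A1, which encodes the main eIF4A isoform, was read far more than its paralog EIF4A2 or than DDX3X in every line under DMSO. EIF4A1 stood at 7030 ± 259 CPM (SD, n = 2) in A375, 3772 ± 107 in NCI-H520, 3521 ± 27.4 in Hs 936.T and 2134 ± 35.8 in NCI-H1650. DDX3X stood at 1161 ± 203 CPM in A375, 1092 ± 17.9 in Hs 936.T, 996 ± 230 in NCI-H520 and 737 ± 39.6 in NCI-H1650. EIF4A2 was highest in NCI-H520, at 929 ± 32.5 CPM, and lay between 209 and 262 CPM in the other lines. Between the lung lines, EIF4A1 was lower in NCI-H1650 than in NCI-H520 by a log2 difference of -0.82 ± 0.08 (SE) and EIF4A2 by -1.82 ± 0.12. Between the melanoma lines, EIF4A1 was lower in Hs 936.T than in A375 (SE 0.07 log2, adjusted p = 7.1e-16, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). EIF4A2 was higher there by 0.31 ± 0.10, a call that ended without Hs 936.T DMSO replicate 1 (0.28) or A375 DMSO replicate 1 (0.16). DDX3X was lower in NCI-H1650 than in NCI-H520 by -0.44 ± 0.16 (adjusted p = 0.039, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), a call that ended without NCI-H520 DMSO replicate 2 (-0.19), and the melanoma lines gave -0.08 ± 0.14 (adjusted p = 0.63 in the same test). DDX3X lies on chromosome X from 41333284 to 41364472 (GRCh38). It has a closely related copy, with which some reads can be shared.

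With RocA, footprints on EIF4A2 rose in all 4 lines at both doses, by 0.95 ± 0.10 at 0.3 µM and 1.42 ± 0.11 at 3 µM on the log2 scale. EIF4A1 changed little: 0.11 ± 0.09 at 0.3 µM, which was not called (adjusted p = 0.27, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 0.36 ± 0.09 at 3 µM, which was. DDX3X was not called at either dose, with 0.30 ± 0.46 at 0.3 µM and -0.36 ± 0.49 at 3 µM. At 0.3 µM the lines were apart: the DDX3X change was 1.96 in A375 and lay between -1.02 and -0.44 in the other lines, and without the A375 library at 0.3 µM the estimate became -0.73.

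**Figure D2:**
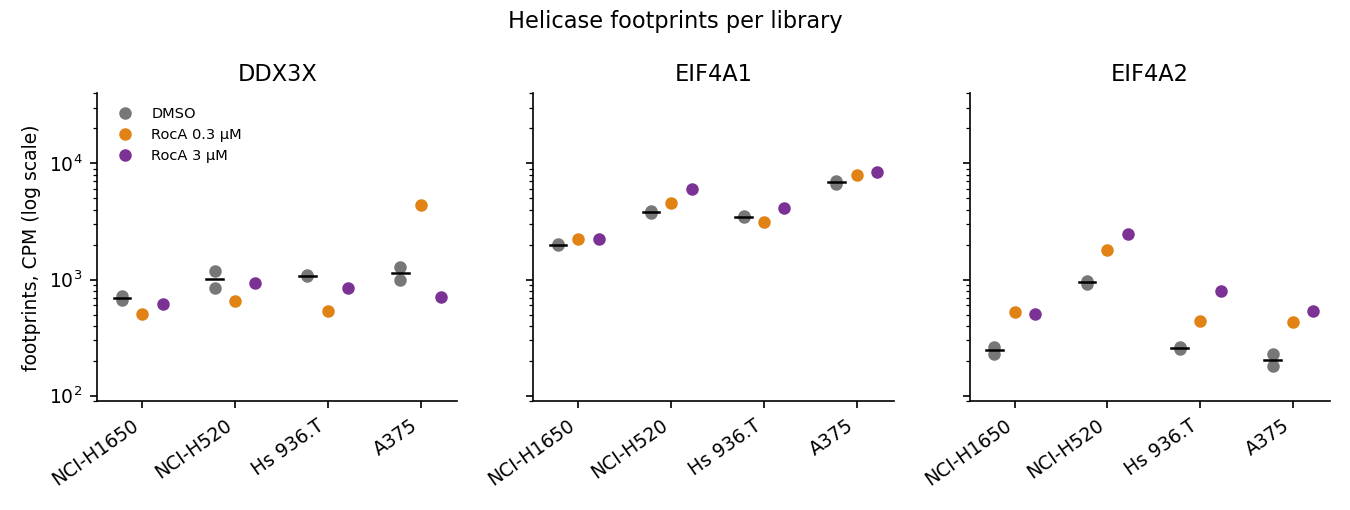
Footprints on DDX3X, EIF4A1 and EIF4A2 in each of the 16 libraries (CPM, log scale), by cell line and treatment; points are libraries and the black bars are means of the DMSO libraries. EIF4A2 lies above its DMSO level in every treated library, and DDX3X in A375 at 0.3 µM stands 1.96 log2 units above its DMSO mean.

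What 0.3 µM RocA did to the footprints of each gene was tested across the 4 lines. The largest rises were on RPS6KB2, which encodes a ribosomal protein S6 kinase (3.06 ± 0.35 log2), on ZFP36, which encodes an mRNA decay factor of the early response to stimuli (3.05 ± 0.24), on the filamin gene FLNC (2.84 ± 0.43), on AHNAK (2.55 ± 0.28) and on the dynein heavy chain gene DYNC2H1 (2.30 ± 0.16). Each rose in all 4 lines, as did TADA2B, C22orf39, GUK1 and ABTB1 among the 10 largest. The falls with adequate counts were led by the ubiquitin-conjugating enzyme gene UBE2D3 (-3.49 ± 0.25) and the lipid kinase gene PIP5K1A (-3.34 ± 0.26). The other 8 of the 10 largest falls rested on 1 to 3 counts over the 4 treated libraries: NEK1 fell to a level 23.4-fold below DMSO (95% counting interval 4.19 to 923), and FAM72A, FAM72B, SANBR, SEMA3E, SLC38A9, DEDD and KLK6 had ratios between 11.5-fold and 14.4-fold. FAM72A and FAM72B are near-identical copies and their reads cannot be told apart with certainty. Of 5964 genes tested, 1448 were called higher and 2148 lower (adjusted p under 0.05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), with a median over all tested genes of -0.19. With the libraries of each line thinned to equal depth, an alternative chosen after the data were seen, 1268 of 4653 genes were higher and 1314 lower, with a median of -0.03, so the excess of lower calls nearly vanished. By at least 2-fold, 601 were higher and 1350 lower. Of the 3596 calls, 3005 (83.6%) had the same sign in each of the 4 lines.

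The translation machinery split at 0.3 µM. Of 38 cytosolic ribosomal protein genes, 21 rose, 7 fell and 10 were not called, counts that were the same adjusted over the list alone; RPL36A rose by 1.30 ± 0.10 and RPL3 by 1.12 ± 0.08, while RPL7 fell (-1.18 ± 0.10). The list as a whole was shifted upward (adjusted p = 0.0098, camera with a preset correlation of 0.01), with adjusted p = 0.78 with an estimated correlation. Of 16 other mRNAs that begin with a terminal oligopyrimidine (TOP) tract, 8 rose and 6 fell, also adjusted over the list alone. Among them, EIF4B rose by 1.61 ± 0.09 and EIF2A by 1.38 ± 0.11, while the poly(A)-binding protein gene PABPC1, read on a short entry of 121 codons, fell (-1.71 ± 0.11) together with RACK1 (-1.01 ± 0.10). Of 11 genes of eIF4A, DDX3 and the cap-binding complex, 3 rose and 3 fell, adjusted over the list alone too. The falls included PDCD4, an inhibitor of eIF4A (-2.22 ± 0.22), and EIF4G2 (-1.91 ± 0.13). Of 12 translation initiation factor genes, 5 rose and 5 fell, over all genes and adjusted over the list alone, with EIF5 at -2.39 ± 0.20, EIF2B3 at -1.14 ± 0.18 and EIF3L at 0.83 ± 0.10. Of 15 aminoacyl-tRNA synthetase genes, 6 rose and 4 fell, among them QARS1 (1.53 ± 0.11) and RARS1 (-0.84 ± 0.12). The other DEAD/DEAH-box helicases went up on balance: 15 of 34 rose, 16 adjusted over the list alone, and 7 fell, with DDX52 at 1.49 ± 0.11 and DDX39A at -1.29 ± 0.13. Their shift had adjusted p = 0.031 by camera, and adjusted p = 0.59 with an estimated correlation.

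Proto-oncogenes and survival genes lost footprints at 0.3 µM. Of 20 tested, 14 fell, 2 rose and 4 were not called, over all genes and adjusted over the list alone, and the median of the list was -1.15. The transcription factor genes ETS1 (-2.52 ± 0.22) and HIF1A (-2.25 ± 0.18) fell, and so did the apoptosis inhibitor gene BIRC2 (-1.71 ± 0.45). The downward shift of the list had adjusted p = 0.017 by camera and adjusted p = 0.20 with an estimated correlation. Spliceosome and SR protein genes fell as well: 11 of 15, or 12 adjusted over the list alone, were lower and 2 higher, with TRA2A at -2.09 ± 0.20, PRPF19 at -1.29 ± 0.14 and SRSF5 at -1.13 ± 0.13. For that list camera gave adjusted p = 0.030, and adjusted p = 0.59 with an estimated correlation; the call ended when Hs 936.T was left out. Of 24 nuclear-encoded genes of oxidative phosphorylation, 17 rose and 4 fell, over all genes and adjusted over the list alone. SDHA (1.41 ± 0.10), COX7A2 (1.30 ± 0.11) and ATP5F1B (1.30 ± 0.08) rose, and SDHD fell (-1.57 ± 0.16). This list had the smallest adjusted p of the 23 tested, 2.4e-05 by camera, and adjusted p = 0.20 with an estimated correlation. Of 11 glycolysis genes, 5 rose, including LDHA (1.68 ± 0.08), GPI (1.62 ± 0.08) and PFKP (1.46 ± 0.11), and 4 fell, also adjusted over the list alone, with adjusted p = 0.0098 by camera and adjusted p = 0.59 with an estimated correlation. The glycolysis call also ended without Hs 936.T.

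Further lists were not called by camera at 0.3 µM, though a rotation test (fry) called 12 lists against 6, among them cholesterol synthesis, the proteasome, the integrated stress response and endoplasmic reticulum chaperones. Of 13 cholesterol synthesis genes, 6 fell, among them SQLE (-2.13 ± 0.27) and FDFT1 (-1.57 ± 0.15), and 2 rose. Of 14 cytosolic chaperone genes, 4 rose and 6 fell; subunits of the chaperonin TRiC went in opposite directions, with CCT3 (1.12 ± 0.09) and CCT5 (1.12 ± 0.09) up and CCT7 (-1.03 ± 0.10) down. Of 16 proteasome genes, 2 rose and 5 fell, with PSMD1 at -1.75 ± 0.13 and PSMD8 at 0.82 ± 0.09. Of 9 integrated stress response genes, 5 rose and 2 fell, with MTHFD2 at 1.38 ± 0.09. Of 10 immediate early genes, 1 rose (ZFP36) and 4 fell, among them SPRY4 (-1.29 ± 0.21) and DUSP6 (-1.25 ± 0.18). Of 9 endoplasmic reticulum chaperone genes 4 rose and 3 fell, of 20 genes of S and M phase 4 rose and 8 fell, of 12 extracellular matrix genes 6 rose and 1 fell, and of 6 transcripts reported as DDX3-dependent 2 rose and 3 fell. Among lineage genes, 6 of 10 melanocyte genes fell and none rose, 3 of 8 epithelial genes rose, 1 of 5 squamous genes rose and 1 fell, and 3 of 7 mesenchymal genes rose and 1 fell. The members called for these lists were the same in number adjusted over the list alone. By line, the melanocyte median was -2.27 in NCI-H520, -0.68 in Hs 936.T, 0 in NCI-H1650 and 0.01 in A375. The melanocyte share of the NCI-H520 DMSO libraries given above stands beside the largest of these falls. Median and mean differed in sign for the cap-binding complex list (mean -0.09), endoplasmic reticulum chaperones (0.10), initiation factors (-0.18) and squamous genes (-0.22). None of the 6 lists called at 0.3 µM was called with an estimated correlation, a setting meant to allow for genes of a list that move together. For proto-oncogenes and survival genes that estimate was -0.026, below the preset value, yet the camera adjusted p rose from 0.017 to 0.20. Joint movement of these genes therefore cannot be why that call ended. The other lists called had estimates from 0.10 to 0.55, and why their calls ended was not tested.

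At 3 µM the same question was asked at the higher dose. ZFP36 had the largest rise (3.53 ± 0.26), followed by the splicing regulator gene RBFOX1 (3.08 ± 0.26), RPS6KB2 (2.98 ± 0.39), C22orf39 (2.88 ± 0.28) and the zinc finger gene ZNF83 (2.87 ± 0.31). RBFOX1 and ZNF83 were read on short entries of 64 and 116 codons, so these values are not changes over the whole coding sequence. The 10 largest falls all lay near the limit of detection. RAB29 had 0 counts in the 4 treated libraries and was at least 8.77-fold lower than DMSO, where 3 counts over those libraries set the limit; KLHL8 was at least 6.08-fold and GULP1 at least 5.33-fold lower. TBC1D5, SLC16A7, PKMYT1, PRIMPOL and CDIPT kept 1 or 2 counts. For the cell cycle kinase gene PKMYT1 the ratio was 34.8-fold (95% counting interval 9.64 to 287). Of 5964 genes, 1326 were called higher and 2029 lower by the same test, with a median of -0.22 (1325 higher and 1351 lower after thinning, median -0.02), and 2741 of the 3355 calls (81.7%) had the same sign in each line. By at least 2-fold, 601 were higher and 1397 lower.

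Gene groups were then counted at 3 µM. Of the 38 ribosomal protein genes, 23 rose and 7 fell, or 24 and 8 adjusted over the list alone, with RPL37A at 0.93 ± 0.11. Camera gave adjusted p = 0.0019 for the list, and adjusted p = 0.85 with an estimated correlation. Among other TOP mRNAs, 8 of 16 rose and 6 fell, also adjusted over the list alone. RACK1 fell by 1.89 ± 0.11 on the log2 scale and PABPC1 by 1.93 ± 0.12, while EIF4B rose by 1.73 ± 0.10. Proto-oncogenes and survival genes fell in 11 of 20 cases and rose in 2, over all genes and adjusted over the list alone, with ETS1 at -2.96 ± 0.28, HIF1A at -2.76 ± 0.21 and ROCK1 at -2.34 ± 0.53. That list had adjusted p = 0.032 by camera and adjusted p = 0.41 with an estimated correlation. Oxidative phosphorylation genes rose in 13 of 24 cases, 14 adjusted over the list alone, and fell in 4, with UQCRB at 1.56 ± 0.10 and NDUFC2 at -1.76 ± 0.15 (adjusted p = 4.9e-04 by camera, and adjusted p = 0.41 with an estimated correlation). Spliceosome genes fell in 11 of 15 cases and rose in 2, with TRA2A at -2.78 ± 0.27 and SF3B1 at 1.06 ± 0.10 (adjusted p = 0.035 by camera, and adjusted p = 0.74 with an estimated correlation). The DEAD/DEAH-box helicases rose in 14 of 34 cases and fell in 6, with DDX27 at 1.37 ± 0.13 (adjusted p = 0.032 by camera, and adjusted p = 0.74 with an estimated correlation). Both lists had the same counts adjusted over the list alone. The helicase call ended without NCI-H520, and the spliceosome call without NCI-H1650 or without A375. Glycolysis was not called at this dose (adjusted p = 0.094 by camera), though LDHA (1.49 ± 0.08) and GPI (1.19 ± 0.08) rose. The remaining lists were not called. Immediate early genes had 3 higher and 5 lower of 10 (4 and 6 adjusted over the list alone), aminoacyl-tRNA synthetases 7 and 3 of 15 (7 and 4), and S and M phase genes 5 and 4 of 20 (4 and 4). The others had equal counts either way: eIF4A, DDX3 and the cap-binding complex 4 and 3 of 11, integrated stress response 5 and 2 of 9, cytosolic chaperones 5 and 6 of 14, endoplasmic reticulum chaperones 2 and 2 of 9, proteasome 6 and 5 of 16, glycolysis 5 and 3 of 11, cholesterol synthesis 1 and 7 of 13, extracellular matrix 5 and 1 of 12, initiation factors 4 and 5 of 12, DDX3-dependent transcripts 2 and 1 of 6, melanocyte genes 0 and 5 of 10, epithelial genes 3 and 1 of 8, squamous genes 1 and 1 of 5, and mesenchymal genes 2 and 1 of 7. The melanocyte median by line was -1.28 in NCI-H520, -0.65 in Hs 936.T, 0 in NCI-H1650 and 0.67 in A375. The same limit of the NCI-H520 DMSO libraries holds here. Median and mean differed in sign for the proteasome (mean -0.08), initiation factors (-0.24) and squamous genes (-0.28). As at 0.3 µM, none of the 5 lists called was called with an estimated correlation.

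**Figure D3:**
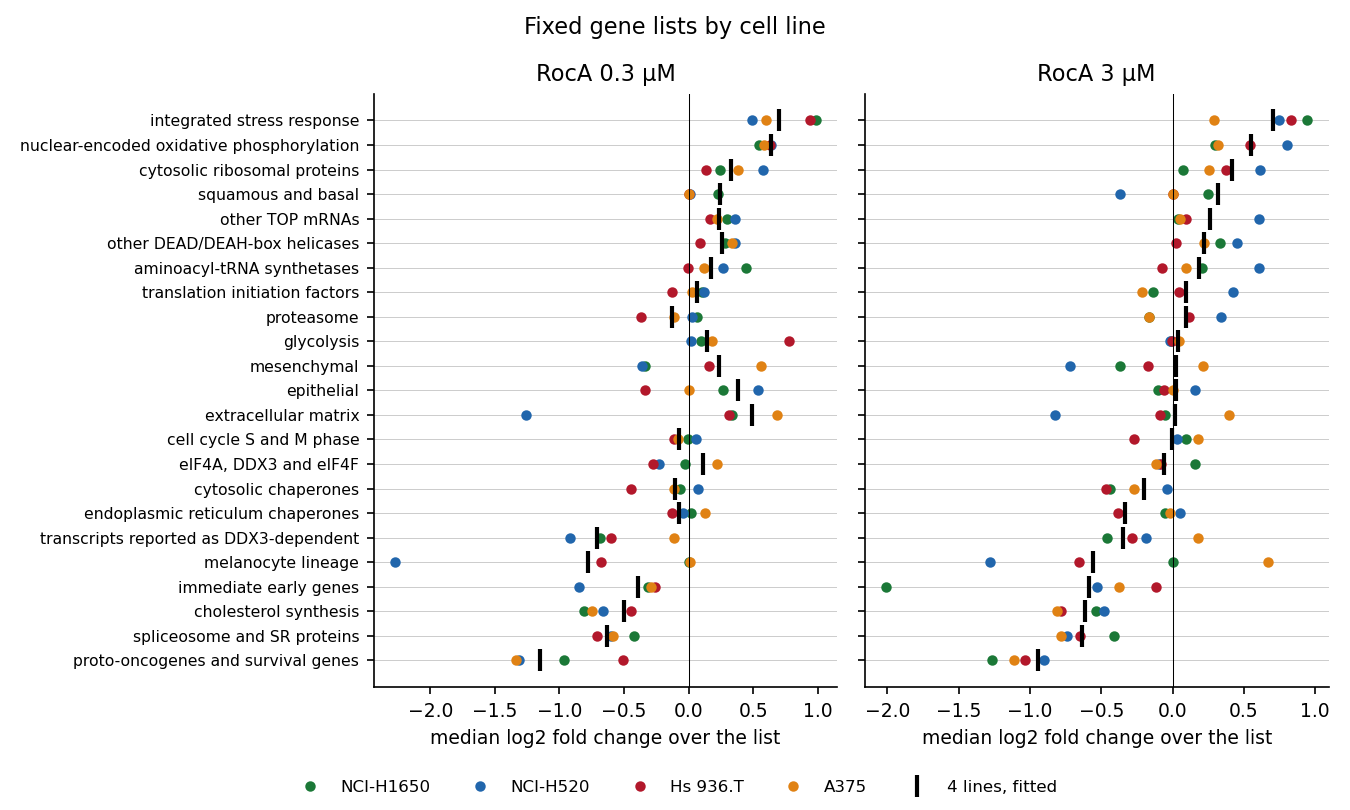
Median log2 fold change against DMSO over each of the 23 fixed gene lists (horizontal axis) at 0.3 µM (left) and 3 µM (right); coloured points are the 4 cell lines and black bars are medians of the fold changes fitted over the lines. Proto-oncogenes and spliceosome genes lie below 0 and oxidative phosphorylation genes above 0 in every line at both doses.

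The doses gave closely related responses. ZFP36 and RPS6KB2 were among the largest rises at both. Of the genes tested, 1074 were called higher at both doses and 1706 lower at both, and 13 were called in opposite directions. Independent lists of these sizes would share 322 and 731 genes. The fold changes of the doses correlated across genes at r = 0.858, and genes are not independent replicates. Both doses were set against the same DMSO libraries, which alone gave a mean r of 0.108 in 20 simulations of unchanged groups (highest 0.157) and a mean covariance of 0.0076, where the observed covariance was 0.932. With 0.3 µM set against DMSO replicate 1 and 3 µM against replicate 2, r was 0.895 over 4314 genes. It was 0.900 over 4326 genes with the replicates exchanged. Then 938 and 937 genes were higher at both doses, and 1019 and 1070 lower. Fewer genes passed the count filter there than the 5964 above, so these values do not compare directly with the main ones. Few genes differed between 3 and 0.3 µM: 58 were higher and 116 lower at 3 µM by the same test. The higher ones included FAAP24 (2.81 ± 0.61), ZNF83 (1.74 ± 0.38) and GALNT15 (1.40 ± 0.28, on a short entry of 73 codons), and the lower ones PTPRU (-2.49 ± 0.64), HES6 (-2.36 ± 0.56) and SLC43A3 (-2.05 ± 0.47), all on fewer than 100 counts per dose. EIF4A2 was higher at 3 µM by 0.48 ± 0.13 (adjusted p = 0.025, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), a call that ended without any 1 of the treated NCI-H520 or Hs 936.T libraries (0.36 without Hs 936.T at 3 µM) and without A375. ZNF83 was no longer called without the NCI-H520 library at 3 µM (0.92). Without Hs 936.T, 9 genes were higher and 20 lower at 3 µM, and both counts also fell by over 1.5 times without the NCI-H520 library at 3 µM (21 and 52).

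**Figure D4:**
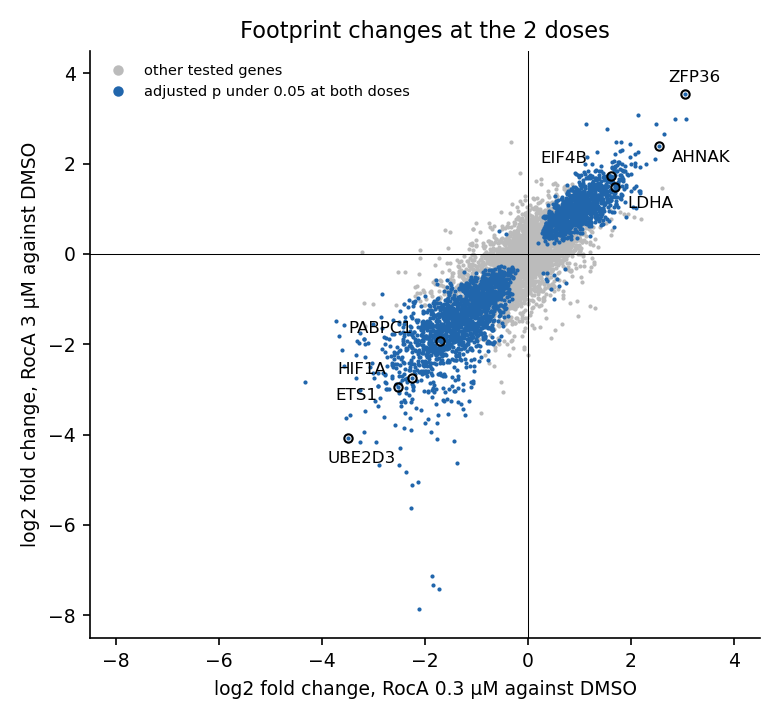
Log2 fold change against DMSO at 0.3 µM (horizontal axis) and at 3 µM (vertical axis), 1 point per gene for 5964 genes; blue points were called at both doses and circles mark named genes. The points follow the diagonal, with r = 0.858, and 13 genes were called in opposite directions.

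Because RocA clamps eIF4A on purine runs, the response was compared with the annotated 5' untranslated region (5' UTR) of 5957 genes. Genes whose 5' UTR held many purine runs lost footprints. With no 6-mer made only of A and G in the 5' UTR, the median change at 0.3 µM was 0.41, and with 16 or more such 6-mers it was -0.79. Spearman's rho across genes between the change at 0.3 µM and the number of purine 6-mers was -0.41, with the longest purine run -0.38, with the length of the 5' UTR -0.38 and with its GC content 0.18. At 3 µM the values were -0.36, -0.33, -0.36 and 0.07. Each of these 8 relations had a permutation p and an adjusted p of 1e-05, the smallest that 100000 permutations can give, and genes are not independent replicates. Long 5' UTRs hold more purine runs by size alone: given length and GC content, the partial rho of purine 6-mers was -0.18 at 0.3 µM and -0.15 at 3 µM, and that of the longest run -0.17 and -0.14. These relations were not adjusted for the mean footprint level of a gene and were not run on thinned libraries.

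**Figure D5:**
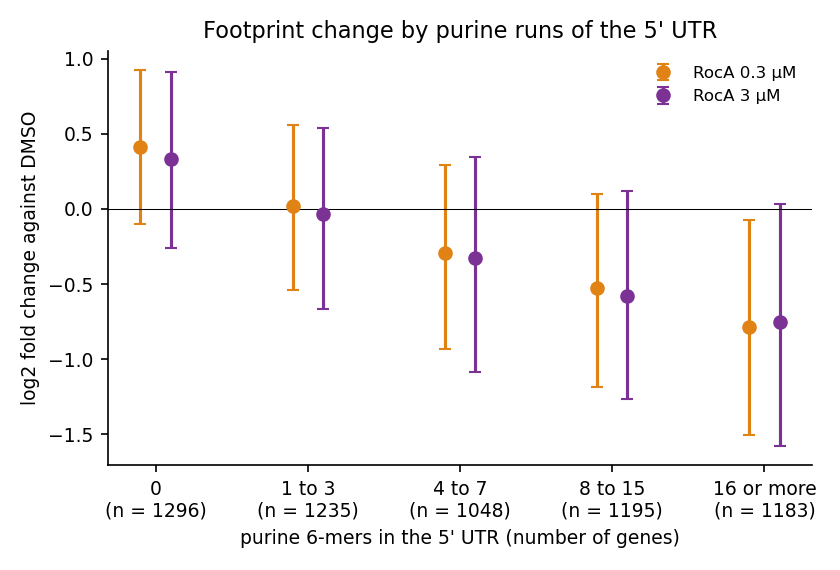
Log2 fold change against DMSO (vertical axis) by the number of purine 6-mers in the annotated 5' UTR (horizontal axis, number of genes in brackets); points are medians and bars span the first to the last quartile. The median falls from 0.41 to -0.79 at 0.3 µM and from 0.33 to -0.75 at 3 µM.

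Whether the lines answered RocA differently was tested with both doses joined, so that each line had 2 treated libraries. Values are the log2 change in the first line less that in the second, so a sign gives no size of response. Between NCI-H1650 and NCI-H520, the spectrin gene SPTBN1 differed by 2.48 ± 0.45, with a mean change of 2.29 in the former and -0.22 in the latter. The kinetochore gene DSN1 differed by 3.27 ± 0.82, with mean changes of -0.64 and -3.70, and ANKRD11 by 3.16 ± 0.82. Both rest on few counts in the treated libraries of NCI-H1650 and NCI-H520, 12 and 4 for DSN1 and 11 and 6 for ANKRD11. The RNA-binding protein gene PCBP2 differed by -1.63 ± 0.26, with mean changes of -1.72 in NCI-H1650 and -0.15 in NCI-H520, and the cohesin gene RAD21 by -0.87 ± 0.21 (-0.59 and 0.29). MSRB1 (-1.74 ± 0.43), DDX19B (-1.32 ± 0.34) and RPL28 (-1.01 ± 0.20) differed in the same direction. Between Hs 936.T and A375, the utrophin gene UTRN differed by -2.93 ± 0.38, with mean changes of -1.37 and 1.45. The tropomyosin gene TPM1 differed by -2.08 ± 0.54 (-1.28 and 0.64), with 6 counts in the treated Hs 936.T libraries. The immediate early gene FOS differed by -2.15 ± 0.43 (-0.06 and 2.17) and the intermediate filament gene SYNM by -1.83 ± 0.49 (-0.12 and 1.68). The 6 largest positive differences of the melanoma pair, among them SLC39A11 and RARA, had 0 counts in the treated A375 libraries. In all, 207 of 5964 genes differed between the 4 lines, 24 between the lung lines (16 positive, 8 negative) and 74 between the melanoma lines (39 and 35). None of the 12 genes given with values above was called with dose as a score in edgeR, where 338 genes differed between the 4 lines at an unadjusted p under 0.05 and 0 after adjustment. Without a common dose term 4 of the 12 were called (SPTBN1, PCBP2, UTRN and FOS), and 74 genes differed between the 4 lines. DDX3X, EIF4A1 and EIF4A2 were not among those called in either pair. Many of the libraries moved these counts by over 1.5 times, between 3 and 28 (positive) and 1 and 40 (negative) in the lung pair and between 2 and 62 and 12 and 39 in the melanoma pair: without the A375 library at 0.3 µM, 2 and 12 genes differed between the melanoma lines, and without NCI-H1650 at 0.3 µM, 3 and 40 between the lung lines. On simulated counts a 2-fold difference of response was recovered for 4.48% of genes in the lung pair, where 15.2% of calls were false, and for 25.4% in the melanoma pair.

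Under DMSO the melanoma lines were compared first. Hs 936.T carried the pigment program: PMEL was higher than in A375 by 10.30 ± 0.70 on the log2 scale, DCT by 10.32 ± 0.36, TYRP1 by 9.95 ± 0.48 and SLC45A2 by 9.88 ± 0.45, and all 10 melanocyte genes tested were higher, also adjusted over the list alone (adjusted p = 0.37 with an estimated correlation). The myelin gene MBP, with 0 counts in A375, was at least 577-fold higher in Hs 936.T, GYG2 at least 351-fold and the apoptosis inhibitor gene BIRC7 at least 321-fold. A375 held the mesenchymal and matrix genes: the neuropilin gene NRP1 was at least 224-fold lower in Hs 936.T, FN1 stood at -7.81 ± 0.43 and CDH2 at -3.45 ± 0.14 on the log2 scale, and the receptor gene AXL had 3 counts there against 1535, a ratio of 434-fold (95% counting interval 149 to 2107). Of 13 extracellular matrix genes 10 were lower and 2 higher in Hs 936.T, and of 7 mesenchymal genes 6 were lower and 1 higher, over all genes and adjusted over the list alone. For these lists the adjusted p was 0.49 and 0.37 with an estimated correlation. Of 24 oxidative phosphorylation genes 15 were higher and 4 lower, and of 13 cholesterol synthesis genes 9 and 2, also adjusted over the list alone (adjusted p = 0.49 and 0.37 with an estimated correlation). In all, 2254 of 7089 genes were higher and 2322 lower in Hs 936.T.

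Between the lung lines, NCI-H1650 carried the epithelial genes. KRT8 was higher there than in NCI-H520 by 2.33 ± 0.08 on the log2 scale, KRT19 by 2.01 ± 0.08 and the cadherin gene CDH1 by 3.00 ± 0.11, and 6 of 8 epithelial genes were higher and 1 lower (2 lower adjusted over the list alone). The squamous and basal genes KRT15 (4.05 ± 0.46) and KRT17 (1.89 ± 0.39) were higher too, 4 of 5 tested, as were 10 of 13 extracellular matrix genes. The antiviral gene TRIM22 had 0 counts in NCI-H520 and was at least 51.2-fold higher in NCI-H1650. NCI-H520 was higher in 17 of 20 genes of S and M phase, 13 of 16 proteasome genes, 24 of 38 ribosomal protein genes (25 adjusted over the list alone) and 9 of 11 genes of eIF4A, DDX3 and the cap-binding complex. The neuronal hydrolase gene UCHL1 was higher in NCI-H520 as well, with a log2 difference of -5.43 ± 0.68. All these lists were called by camera, and none with an estimated correlation (adjusted p = 0.29 for each). Camera with that setting called no list in either pair. It missed even the melanocyte genes of the melanoma lines (median 9.29 log2, adjusted p = 0.37 by that test). Losing a call there thus says little about a list. VIM (-3.44 ± 0.46) and all 10 melanocyte genes were lower in NCI-H1650 too, where the melanocyte share of the NCI-H520 DMSO libraries given above stands beside them. In all, 2103 genes were higher and 2053 lower in NCI-H1650. The other pairs of lines differed in 4873 genes (NCI-H1650 and Hs 936.T), 4469 (NCI-H1650 and A375), 4272 (NCI-H520 and Hs 936.T) and 3970 (NCI-H520 and A375).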

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

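The tests of index misassignment for the melanocyte genes and of a pile-up of reads on DDX3X were chosen only after the result was seen.

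Melanocyte genes stood out in NCI-H520, a lung line, with a median over 9 genes of 3.92% and 8.32% of the Hs 936.T level in the DMSO replicates, against at most 0.598% in NCI-H1650 and A375. If reads of Hs 936.T were mixed in, other genes particular to Hs 936.T would follow, and 100% of 5 such genes outside the list (CAPN3, GPM6B, PPARGC1A, RENBP and SLC24A5) stood at no less than 0.5 times that share in NCI-H520; as several of them belong to pigment cells, they would follow if NCI-H520 translated that programme too, so this does not tell mixing from own translation. Translation of these genes by NCI-H520 itself would give the replicates like levels if both held the same cells. The median log2 ratio of replicate 2 to replicate 1 was 1.02 (95% interval over the 5 genes 0.82 to 1.22), so levels were unlike. It was -0.03 over 669 genes abundant in NCI-H520 and lower in Hs 936.T. Replicate 2 carries the label NCI-H521 and there was 1 pair of libraries, so this cannot decide against own translation. Misassigned index reads over all libraries would reach NCI-H1650 as well, where the share was 0.142 of that in NCI-H520 DMSO replicate 1. Some Hs 936.T material or reads in the NCI-H520 DMSO libraries may be the source, without a test that only mixing would pass. Own translation is not excluded, and both stay open.

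DDX3X changed by 1.96 in the A375 library at 0.3 µM while the other lines lay between -1.02 and -0.44. A pile-up of reads at 1 place was tested over its 15 coding entries, of which the lowest rose by 1.54; as entries repeat reads, each of 5 short ones was also set beside the rest of the full-length entry, which rose by 1.72 or more without it, provided the short entries lie within it. Nor was it a library in which many genes deviate as far: 0.252% of 3967 genes did. With 1 library for that line and dose, a sampling or handling effect on this gene and a real response may each be the cause. Reads of a related copy were not examined, and no biological explanation was tested.

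The genes that responded differently in Hs 936.T and A375 had long coding sequences, with a median of 877.5 codons against 531 for all tested genes. More counts, and so more power, for long sequences may be a cause, but random lists matched for mean CPM had a median of 499.5 codons and the real one was at percentile 100 of them. Unequal depth was examined by thinning libraries to equal totals within each line. Genes of 2000 codons or more then kept 105.6% of their median response difference (-0.19 log2 beside all genes, both doses joined). Thinning lowers counts but leaves the expected fold change as it is, so this outcome was nearly fixed and cannot decide on depth. The lengths of the genes called after thinning were not examined. By dose, genes of 2000 codons or more lay at 0.17 in Hs 936.T and 0.19 in A375 at 0.3 µM, and at -0.12 and 0.34 at 3 µM. The difference was thus seen only at 3 µM, with 1 library per line. Of 15 such genes among the 74, 14 had a more negative change in Hs 936.T. A slower or later block in 1 line is among the open explanations and was not tested.

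Differences of response between lines were found by a test of the difference itself: 207 genes over the 4 lines, 24 between the lung lines and 74 between the melanoma lines. In the lung pair these included DSN1 (3.27), ANKRD11 (3.16), SPTBN1 (2.48), MSRB1 (-1.74), PCBP2 (-1.63), DDX19B (-1.32), RPL28 (-1.01) and RAD21 (-0.87). In the melanoma pair they included UTRN (-2.93), FOS (-2.15), TPM1 (-2.08) and SYNM (-1.83).

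Of 55 groups of values tested for 1 far from the others, 5 had such a value, where chance gives about 1 in 20 groups (2.75 here). Immediate early genes at 0.3 µM had a median change of -0.85 in NCI-H520. Squamous and basal genes at 0.3 µM had 0.22 in NCI-H1650, beside 0.01 in NCI-H520 and 0 in Hs 936.T and A375. Several of these genes had few or no DMSO counts in Hs 936.T and A375 (TRIM29 0 and 0, KRT17 5 and 7), so a change could hardly be seen there. Other TOP mRNAs at 3 µM had 0.61 in NCI-H520. The list of eIF4A, DDX3 and the cap-binding complex at 3 µM had 0.16 in NCI-H1650. The total count at 3 µM was lowest in NCI-H1650, at 47366.

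Loci other than those representing a named gene also carried a signal. Of 17663 loci tested, 12002 did not represent a named gene, and 3815 of these were higher and 3904 lower at 3 µM. Whether such a locus held further entries of a named gene was not tested, so these are numbers of loci and not of unnamed genes.

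Treatment labels were rearranged within cell lines in 81 ways. At 0.3 µM the real arrangement called 3596 genes and the highest other 355, with 1 of 81 as large. At 3 µM it called 3355 and the highest other 1351, again 1 of 81. Both shares were under 0.05. Every other arrangement set at least 1 treated library among the DMSO libraries. Each treated library also had a lower total than the DMSO libraries of its line, so the rearrangements do not separate RocA from depth. Depth was examined by thinning instead. For the gene lists at 0.3 µM, 3 of 81 arrangements called as many as the 6 real ones (highest other 6), a share under 0.05. At 3 µM 5 of 81 called as many as the 5 real ones (highest other 6). An arrangement with the real label in 0 lines called 5 lists at each dose. Chance therefore cannot be excluded for the lists at either dose. Between the doses, 174 genes were called and at most 63 in another of the 8 arrangements, of which 1 was as large; these are too few for a share under 0.05.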

How the results depend on the processing

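Thinning to equal depth, all loci, and the estimated correlation for the DMSO lists were chosen only after the data were seen. Unless a value shows the cause, the cause was not tested.

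At 0.3 µM the 1448 higher and 2148 lower genes became 398 and 640 without a term for cell line, and 5123 and 6045 over all loci, where more features were tested. At a minimum count of 50, with 2823 genes tested, 973 were higher and 1049 lower, and after thinning 1268 and 1314, so the excess of lower calls nearly vanished (median -0.03 after thinning, -0.19 before). At 3 µM the counts were 426 and 659 without the cell line term and 4903 and 6220 over all loci, 937 and 1021 at a minimum of 50, and 1325 and 1351 after thinning. Thinned and full fold changes correlated across genes at r = 0.979 and 0.991, with 2490 and 2533 genes called in both and 0 of opposite sign (edgeR). Leaving out 1 library or line gave 1278 to 1576 higher and 1722 to 2167 lower genes at 0.3 µM, and 1161 to 1474 and 1569 to 2060 at 3 µM. Genes lower at both doses numbered 1019 of 4314 and 1070 of 4326 with split controls, where fewer genes were tested than the 5964 of the main comparison.

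Between doses, 58 genes were higher and 116 lower at 3 µM. The higher ones numbered 114 by limma-voom, 101 at a minimum of 50, 101 with the compared libraries alone, 20 with entries summed, 15 without the NCI-H521-labelled libraries and 220 over all loci; the lower ones 45, 75 and 413 in the last 3. Without the cell line term edgeR called 0 in each direction, with 56 higher and 93 lower at an unadjusted p under 0.05. Leave-one-out counts were 9 to 83 and 20 to 160. They were 21 and 52 without NCI-H520 at 3 µM, 23 and 65 without Hs 936.T at 0.3 µM, 16 and 29 without Hs 936.T at 3 µM, and 9 and 20 without Hs 936.T altogether.

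Response differences over the 4 lines (207) became 74 without a dose term, 118 after thinning and 0 with a dose score in edgeR (338 at an unadjusted p under 0.05; 105 and 158 in the lung pair, 154 and 111 in the melanoma pair), with 153 to 291 on leaving out 1 library. In the lung pair, 16 higher became 0 with the score, 3 without a dose term, 3 without the NCI-H521-labelled libraries and 4 after thinning; 8 lower became 17 by DESeq2, 5 without a filter, 13 at a minimum of 50, 0 with the score, 1 without a dose term, 2 without those libraries and 4 after thinning. In the melanoma pair, 39 higher became 18 by DESeq2, 25 at a minimum of 50, 0 with the score, 10 without a dose term and 12 after thinning, and 35 lower became 16, 17, 0, 12 and 14. Leave-one-out ranges were 3 to 28 and 1 to 40 (lung), and 2 to 62 and 12 to 39 (melanoma). The lung pair had 3 and 40 without NCI-H1650 at 0.3 µM, 10 and 1 without it at 3 µM, 5 and 23 without NCI-H520 at 0.3 µM, 2 lower without it at 3 µM, 28 higher without NCI-H520 DMSO replicate 1, and 3 to 5 lower without NCI-H1650 DMSO replicate 2, NCI-H520 DMSO replicate 1 or 2, a Hs 936.T DMSO library or any A375 library. The melanoma pair had 2 and 12 without A375 at 0.3 µM, 22 higher without it at 3 µM, 5 and 62 higher without Hs 936.T at 0.3 and 3 µM, 20 and 21 without Hs 936.T DMSO replicate 1, and 22 lower without A375 DMSO replicate 1.

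Lists called by camera at 0.3 µM (6) and 3 µM (5) were 0 and 0 with an estimated correlation, 12 and 10 by fry, and 1 and 2 without the cell line term; on leaving out 1 cell line, 4 to 8 and 4 to 6 (single libraries were not left out for the lists). Under DMSO the 13 lists called in the lung pair and 8 in the melanoma pair became 0 in both with an estimated correlation. That setting missed even the melanocyte genes of the melanoma pair (median 9.29 log2), so it says little about the other lists. Over all settings, DMSO gene counts ranged from 1623 to 2130 higher (2103 in the main one) and 1650 to 2142 lower (2053) in the lung pair, and from 1707 to 2400 (2254) and 1751 to 2529 (2322) in the melanoma pair; on leaving out 1 library, from 1809 to 2081, 1796 to 2095, 1892 to 2365 and 1893 to 2468.

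Reversed values all concern DDX3X: at 0.3 µM -0.73 without the A375 library at that dose and -0.70 without A375 (leave-one-out range -0.73 to 0.79), between doses 0.40 and 0.48 in the same settings (-1.11 to 0.48), and between the melanoma lines 0.088 without A375 DMSO replicate 1 (-0.26 to 0.088). For single genes, 6510 values kept direction and side of the threshold, 356 lost the call, 11 gained it and 5 reversed. Scaling to mitochondrially encoded genes and the comparison of nuclear with mitochondrially encoded footprints were not run. With this depth, design and spread, a planted 2-fold difference of response was recovered for 4.48% of genes in the lung pair and 25.4% in the melanoma pair.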

Other observations

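The test of coding length was chosen before its result was seen, and purine 6-mers per 100 nt were chosen after the data were seen.

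Members of single protein complexes moved in opposite directions with RocA. In the chaperonin TRiC, CCT3 rose by 1.12 ± 0.09 and CCT5 by 1.12 ± 0.09 on the log2 scale at 0.3 µM, while CCT7 had -1.03 ± 0.10. Among proteasome genes PSMD1 had -1.75 ± 0.13 and PSMD8 0.82 ± 0.09, and among respiratory chain genes SDHA rose (1.41 ± 0.10) while SDHD had -1.57 ± 0.16. At 3 µM CCT3 had 1.09 and CCT7 -1.19.

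Genes without purine 6-mers in the 5' UTR gained in relative terms: of 1296 such genes, 45.9% were called higher and 14.3% lower at 0.3 µM, against 11.1% and 55.7% of 1183 genes with 16 or more. The order of the medians was the same in each of the 4 lines. Per 100 nt, rho was -0.30 at 0.3 µM and -0.25 at 3 µM.

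If initiation was blocked while elongation went on, ribosomes may remain longest on long coding sequences, and the rises on FLNC, AHNAK and DYNC2H1 prompted that hypothesis. As a class, the 245 genes of 2000 or more codons had a median change 0.19 above that of all genes at 0.3 µM, positive in each of the 4 lines, with 78 called higher and 60 lower. At 3 µM the median lay 0.0573 above, with 52 called higher and 74 lower, and the lines split: 0.30 in NCI-H1650, 0.34 in A375, -0.27 in NCI-H520 and -0.12 in Hs 936.T. No steady rise with length was seen: genes under 200 codons lay 0.16 (0.3 µM) and 0.40 (3 µM) above all genes, and the class next to the longest lay at -0.15 and -0.24. The hypothesis had been set to need a median of at least 0.5 at 3 µM in at least 3 lines, which no line reached, and a smaller effect in some lines is not excluded.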
